A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

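The series measured RNA of the budding yeast Saccharomyces cerevisiae on 6 Agilent arrays of 2 channels. Of these, 3 arrays belong to the laboratory strain BY4741, called wild type here, and 3 to a strain that lacks RPD3, the gene of a histone deacetylase. Per the labels' protocols, 3 independent cultures of 200 ml per strain grew to mid-log phase in rich medium, and cells were held at 25 °C or at 39 °C for 20 minutes. RNA (500 ng) was labelled by linear amplification with Cy3 or Cy5. On every array the labels put the 25 °C control in the Cy5 channel and the heated sample in the Cy3 channel, with no exchange of dyes. A dye effect therefore cannot be separated from heat within a strain, while a dye effect common to all arrays cancels in the difference between the strains.

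The values are log ratios of the 2 channels for each spot, deposited by the authors as a table that covers the whole series and read here as log2. The log base and the sign are not stated in the sources used here. Base 2 was taken from the range of the values and from limma, which works in log2 by default and which is named, without a version, per the submitters' processing notes. The sign is likely heated over control, because the design text expresses the response relative to the control. With this reading HSP12, HSP26, HSP104 and SSA4 were positive on all 6 arrays. Given the dyes as labelled, it means Cy3 over Cy5. If Cy5 over Cy3 was deposited instead, the sign or the dye labels would have to be other than read here. If the base were another, every log value and fold would change by 1 common factor on the log scale, and the tests would not. Background correction and normalization within arrays are not given in the sources used here. Scanner intensities were not analysed here, so no filter on dim spots could be set. For arrays, their number limits the precision. The median ratio of all spots was 0.08, 0.04 and 0.03 on wild-type arrays 1 to 3, and -0.03, -0.01 and -0.03 on mutant arrays 1 to 3.

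The table held 45220 spots, of which 10 had no value. The platform's probe table named 28532 spots with 1 gene symbol each and none with several, and the other 16688 spots are unnamed here. The named spots covered 4073 genes, 4070 with 7 spots and 3 with 14. Across genes, the wild-type means of the first and second spot of a gene correlated with r = 0.995, against 0.0049 for randomly paired spots. In all, 124 old symbols were replaced by current ones through the RefSeq gene table of assembly R64, which held 4064 of the 4073 symbols. That table gave names, lengths and the order of genes along chromosomes, and none of its coordinates are printed. Spots of a gene were averaged on each array.

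Tests used limma 3.58.1 in R 4.3.3. All 6 arrays entered 1 fit with a mean per strain and no covariate, and eBayes moderated the variances (4 residual and 3.37 prior degrees of freedom). The 3 contrasts were wild type against 0, rpd3 deletion against 0, and rpd3 deletion minus wild type, which is called the strain difference. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 4073 genes. "Rose" and "fell" refer to such calls. Errors of strain means are SDs over 3 arrays, and errors of strain differences are standard errors of the fit.

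Before the data were examined, 30 gene lists from general knowledge of yeast were fixed. Each was tested in each contrast with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. With the correlation between genes estimated from these few arrays, no list was called in any contrast: the lowest adjusted p was 0.318 in wild type, 0.545 in the mutant and 0.799 for the strain difference. The fry test, which asks whether the genes of a list move on balance in 1 direction, called 26, 21 and 10 lists in these contrasts. To compare the size of the responses, genes of the same sign in 2 wild-type arrays and a mean of at least 2-fold there were taken, and their median in the left-out wild-type array was set against their median in the mean of the mutant arrays.

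Genes are named by a rule fixed in advance. It takes, among called genes of the same sign on all 3 arrays of a strain, the 6 highest and the 6 lowest in each strain. For the strain difference it takes the 8 highest and 8 lowest called genes whose 3 mutant arrays do not overlap the 3 wild-type arrays. It adds the 2 most changed members of a described list in its majority direction and the 1 most opposite member, and 13 genes chosen in advance, among them RPD3, HSP104, CTT1, MSN2, MSN4 and ACT1. Genes named outside this rule are marked as chosen after their values were seen.

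The fit was tested on simulated data for the strain difference, with 4073 genes and 200 changed genes in each of 5 runs. It recovered 33.7% of genes changed by 0.5, 75.8% of those changed by 1 and 97.9% of those changed by 2 on the log2 scale, and 5.1% of its calls were false. The simulated noise was independent between genes, unlike that of the arrays, and had the same size in both strains. The 200 changed genes of a run are also far fewer than the 1866 called for the strain difference here. These rates may therefore not hold for the arrays.

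Alternatives covered centring, scaling, quantile normalization, the median of spots, tests of single spots, robust, absent and separate variance estimates, array weights, a 2-fold minimum, a stricter threshold, the replicate number as a block, and each array left out in turn. After the data were seen, 4 more were added: centring on the genes deleted in BY4741, removal of a trend with gene length, a filter on the spread between spots, and, for the size of the responses, genes chosen on the mutant arrays.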

Results

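The data were 6 arrays, 3 of wild type and 3 of the rpd3 deletion, each setting cells held at 39 °C for 20 minutes against control cells of the same strain at 25 °C. The labels describe the 3 arrays of a strain as biological replicates from independent cultures. All values are log2 ratios, likely of heated over control cells, for 4073 genes. Across genes, which are not independent replicates, ratios correlated with r = 0.952 to 0.980 between wild-type arrays, 0.851 to 0.956 between mutant arrays and 0.504 to 0.853 between strains. The mutant arrays differed in the size of the response: the ratio of HSP12, a small heat shock protein, was 7.15, 8.75 and 5.06 on mutant arrays 1, 2 and 3, against 6.66, 6.08 and 6.43 in wild type.

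RPD3 itself could be checked only weakly, since both channels of a mutant array lack its RNA. Its ratio was 0.22 ± 0.034 (SD, n = 3) in wild type and -0.073 ± 0.040 in the mutant, where it did not differ from 0 (limma adjusted p = 0.355). Its strain difference was -0.29 ± 0.093 (adjusted p = 0.0378). The spread between its 7 spots was 0.034, 0.041 and 0.026 on the wild-type arrays and 0.129, 0.181 and 0.0563 on the mutant arrays. HIS3, LEU2, MET17 and URA3, called the deleted genes here, are absent or cut in BY4741. They were taken as the level of spots without a transcript, though a cut gene could still give some RNA. Their median was 0.15 in wild type and -0.09 in the mutant, and none of the 4 was called in either strain or for the difference.

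The first comparison asked which genes responded to heat in wild type. HSP12 rose most, 83.8-fold (6.39 ± 0.29, SD, n = 3, adjusted p = 4.62e-05). It was followed by ALD3, an aldehyde dehydrogenase (5.71 ± 0.37), HXT5, a hexose transporter (5.58 ± 0.36), TKL2, a transketolase (5.40 ± 0.35), SSA4, a stress-induced Hsp70 chaperone (5.33 ± 0.52), and PHM7 (5.09 ± 0.32). The lowest ratios were those of YHB1, a flavohemoglobin (-3.63 ± 0.20), the ribosomal protein genes RPS26B (-3.46 ± 0.14), RPL9A (-3.01 ± 0.40) and RPL24A (-2.95 ± 0.17), the acid phosphatase gene PHO12 (-3.05 ± 0.35) and NOP13, which encodes a nucleolar protein (-2.99 ± 0.11). In all, 1210 genes rose and 1477 fell, 350 and 487 of them by at least 2-fold. With arrays centred on the deleted genes, an alternative added after the data were seen, 885 rose and 1816 fell, so the share of rises among calls went from 45.0% to 32.8%.

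Stress and reserve-carbohydrate genes rose as groups in wild type. All 41 measured genes of the general stress list, which need the transcription factors Msn2 and Msn4 or carry their element, rose, with a median of 2.65 (camera adjusted p = 4.9e-17; adjusted p = 0.318 with an estimated correlation). They ranged from HSP12 and ALD3 down to SIP18 (0.22 ± 0.07, SE). Of 29 heat shock protein and chaperone genes, 25 rose and 2 fell, with a median of 2.08 (adjusted p = 1.73e-08; adjusted p = 0.337 with an estimated correlation). The small heat shock protein gene HSP26 rose by 4.76 ± 0.43 (SD) and HSP104, the disaggregase gene, by 4.04 ± 0.34, while the mitochondrial co-chaperone gene MGE1 fell by 1.08 ± 0.08. Among 22 genes of trehalose and glycogen metabolism 21 rose, with a median of 2.38 (adjusted p = 1.66e-09; adjusted p = 0.318 with an estimated correlation), led by glycogen phosphorylase GPH1 (4.63 ± 0.49) and phosphoglucomutase PGM2 (4.40 ± 0.36), and PGM1 fell (-0.60 ± 0.10, SE). The catalase gene CTT1 rose by 4.47 ± 0.22 and the trehalose synthase gene TPS1 by 2.65 ± 0.22.

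Further lists rose less in wild type. Respiration genes had a median of 0.52, with 29 of 45 rising and 2 falling (adjusted p = 4.74e-06). The citrate synthase gene CIT1 (2.65 ± 0.43) and SDH1, a subunit of succinate dehydrogenase (1.65 ± 0.14), rose most. Of 30 genes of autophagy and vacuolar proteases 22 rose and 0 fell (median 0.61, adjusted p = 7.8e-06), led by the protease genes PRB1 (2.33 ± 0.14) and APE1 (1.85 ± 0.29). Of 23 meiosis genes repressed through Ume6, the factor that recruits Rpd3 to them, 14 rose and 1 fell (median 0.35, adjusted p = 0.000442). The list also holds metabolic genes, and its most changed members were CAR1 (2.05 ± 0.22) and CAR2 (2.01 ± 0.29) of arginine breakdown, while the meiosis gene SPO16 fell (-0.33 ± 0.098). Stress regulators and the protein kinase A pathway (median 0.59, adjusted p = 0.00108), cell wall genes (0.66, adjusted p = 0.0322), oxidative stress defence (0.41, adjusted p = 0.0185), the proteasome (0.24, adjusted p = 0.0189) and hexose transporters (0.30, adjusted p = 0.0386) were also shifted up. Adjusted p with an estimated correlation was 0.318 to 0.595 for these 8 lists. The call for the proteasome was lost without wild-type array 3 (adjusted p = 0.0666) and with arrays centred on the deleted genes (median 0.10, 0.0558). That for hexose transporters was lost without wild-type array 1 (0.0773) or 2 (0.0719), with fry (0.0961), with the length trend removed (0.0753) and with the filter on spot spread (median 0.58, 0.228).

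Genes of ribosomes and of their assembly fell together in wild type. All 100 measured ribosome biogenesis genes fell, with a median of -1.42 (adjusted p = 1.27e-21; adjusted p = 0.318 with an estimated correlation), from NOP13 and NOP56 (-2.75 ± 0.23, SD) to RCL1 (-0.23 ± 0.07, SE). Of 135 cytosolic ribosomal protein genes 132 fell and 1 rose, with a median of -2.17 (adjusted p = 4.55e-27; adjusted p = 0.318 with an estimated correlation). Of 20 genes of RNA polymerase I and III, the enzymes that make ribosomal and transfer RNA, 19 fell (median -1.06, adjusted p = 2.24e-06), with the lowest ratios in the large polymerase I subunit genes RPA190 (-2.80 ± 0.29) and RPA135 (-2.47 ± 0.24). Translation factors (34 of 40 fell, median -1.06, adjusted p = 9.16e-08) and aminoacyl-tRNA synthetases (16 of 17 fell, median -1.46, adjusted p = 7.8e-06) fell as well. The phosphate regulon (13 of 15, median -1.14, adjusted p = 0.000601), histones (9 of 10, median -0.75, adjusted p = 0.00202), cell cycle genes (22 of 30, median -0.72, adjusted p = 0.00108), amino acid synthesis (38 of 57, median -0.54, adjusted p = 0.00108) and ergosterol synthesis (16 of 24, median -0.55, adjusted p = 0.0118) were also shifted down. Adjusted p with an estimated correlation was 0.318 to 0.410 for these last 8 lists.

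The second comparison asked which genes responded in the rpd3 deletion. The highest ratios were those of HSP12 (6.99 ± 1.85, SD, n = 3, adjusted p = 4.48e-05), SSA4 (5.82 ± 1.29), SSA3, another Hsp70 gene (5.70 ± 1.20), ALD3 (5.35 ± 1.18), the cell wall protein gene SPI1 (4.85 ± 1.48) and HSP104 (4.81 ± 0.85). The lowest were those of the RNA helicase gene DBP2 (-3.80 ± 0.75), PRY1, which encodes a secreted sterol-binding protein (-3.53 ± 0.07), PHO12 (-3.23 ± 0.62), the alcohol acetyltransferase gene ATF2 (-3.21 ± 0.20), and the ribosomal protein genes RPL23A (-3.06 ± 0.13) and RPL21A (-3.03 ± 0.13). In all, 1372 genes rose and 1300 fell, 279 and 373 of them by at least 2-fold. Of these, 754 rose in both strains and 857 fell in both, against 408 and 471 for independent lists of these sizes. The lists are not independent by design, since both strains share 1 variance estimate per gene and the same dye layout. Part of the excess can arise from these alone.

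Camera called 14 of the 30 lists in the mutant. Of 29 heat shock protein and chaperone genes 28 rose and 1 fell (median 2.31, adjusted p = 1.58e-11), of 41 general stress genes 38 rose and 0 fell (median 2.36, adjusted p = 4.74e-13), and of 22 trehalose and glycogen genes 20 rose and 1 fell (median 1.62, adjusted p = 6.09e-07). Of 135 cytosolic ribosomal protein genes 129 fell and 1 rose (median -2.05, adjusted p = 3.67e-31). The ribosome biogenesis list was not called (median -0.05, adjusted p = 0.338): of its 100 genes 33 fell, 15 rose and 52 did not pass the test. The 2 lowest were NOP1 (-1.76 ± 0.10, SD), which encodes fibrillarin, and GAR1 (-1.38 ± 0.34), and the highest was NOP8 (0.74 ± 0.14, SE). Smaller shifts were called for the phosphate regulon (-1.01, adjusted p = 0.000682), histones (-0.83, adjusted p = 0.0133), aminoacyl-tRNA synthetases (-0.64, adjusted p = 0.00258), translation factors (-0.63, adjusted p = 0.000682), amino acid synthesis (-0.44, adjusted p = 0.00142), RNA polymerase I and III (-0.40, adjusted p = 0.0232), ergosterol synthesis (-0.39, adjusted p = 0.047), autophagy and vacuolar proteases (0.38, adjusted p = 0.0322), meiosis genes (0.37, adjusted p = 0.00545) and the proteasome (0.31, adjusted p = 0.0232). Adjusted p with an estimated correlation was 0.545 to 0.615 for these 14 lists. In the list of meiosis genes, 14 of 23 rose and 2 fell; CAR1 (2.17 ± 0.47, SD) and the inositol synthesis gene INO1 (1.95 ± 0.52) had the highest ratios and the meiosis gene SPO13 the lowest (-0.38 ± 0.16). The ergosterol call was lost without wild-type array 1 (adjusted p = 0.0514) or mutant array 2 (0.0791) and with the filter on spot spread (0.0707). With the length trend removed, the calls were lost for histones (median -0.47, adjusted p = 0.119) and for RNA polymerase I and III (-0.27, 0.0944).

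The third comparison asked how the heat ratios of the mutant differed from those of wild type. Each ratio is taken against control cells of the same strain. A strain difference can therefore come from the control level, the heated level or both, and ratios cannot tell these apart. This holds for every gene and list compared here, and an uncalled difference does not show equal levels in the strains. In all, 1012 genes had a higher ratio in the mutant and 854 a lower one, 296 and 177 of them by at least 2-fold. The 3 mutant arrays did not overlap the 3 wild-type arrays for 2378 of 4073 genes, where chance gives 10%, and for 1831 of the 1866 called genes. Without mutant array 1, 643 genes were higher and 450 lower. The lower count was 480 without wild-type array 1 and 507 without wild-type array 2. With arrays centred on the deleted genes, 1564 genes were higher and 398 lower, and the higher share of calls went from 54.2% to 79.7%, so the balance of the directions depends on where 0 is set.

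**Figure D1:**
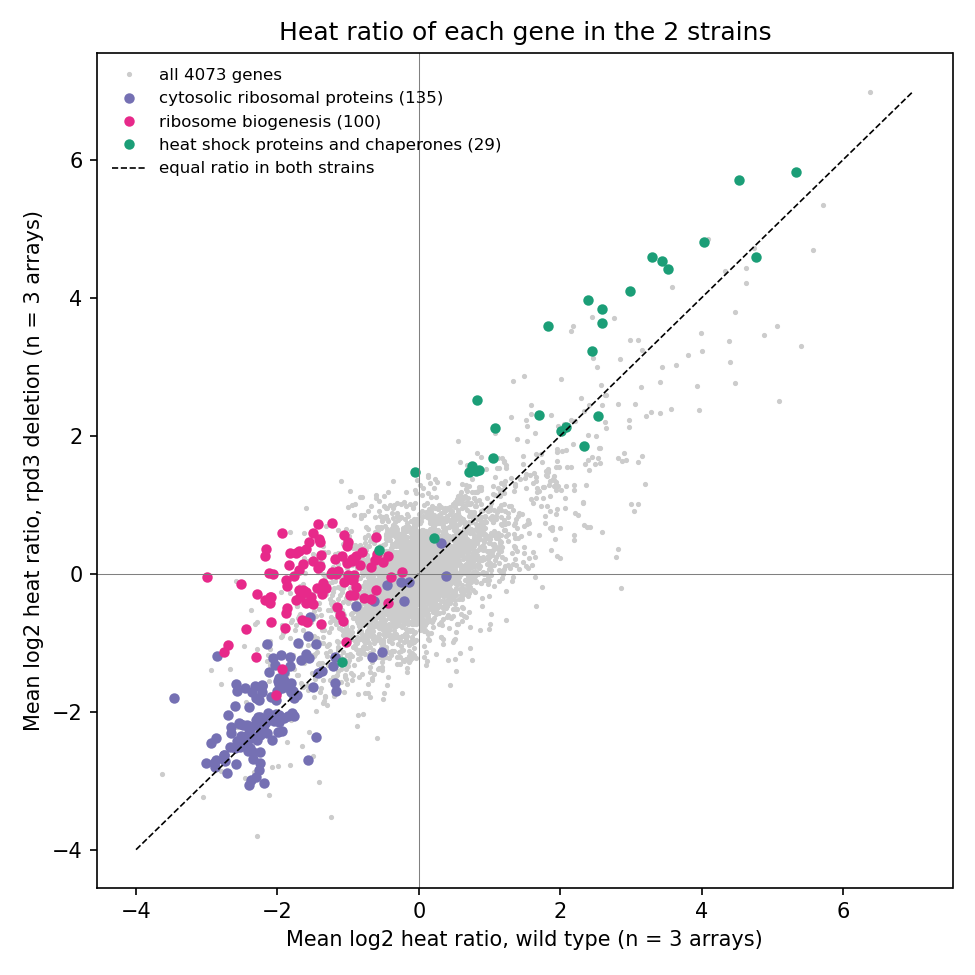
Mean log2 heat ratio of each of 4073 genes in wild type (x axis) and in the rpd3 deletion (y axis), means of 3 arrays each, with 3 gene lists in colour and a dashed line of equal ratios. The ribosome biogenesis genes spread to both sides of 0 on the y axis (median -0.05, SD over genes 0.46) and lie below 0 on the x axis (median -1.42). Ribosomal protein genes lie along the line of equal ratios (medians -2.17 and -2.05).

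The group with the clearest difference was ribosome biogenesis. Its median strain difference was 1.25, with 93 of 100 genes higher in the mutant and 0 lower (97 higher when adjusted over the list alone; camera adjusted p = 1.09e-26; fry adjusted p = 0.00883; adjusted p = 0.799 with an estimated correlation). Per array, its median was -1.37, -1.53 and -1.31 in wild type and -0.11, -0.33 and 0.17 in the mutant. The highest strain differences of all named genes were those of NOP13 (2.95 ± 0.20, SE, adjusted p = 0.000309), SPA2, a scaffold of polarised growth (2.55 ± 0.31, 0.00115), ECM16, an RNA helicase of small-subunit assembly (2.52 ± 0.18, 0.000309), RRP1, a ribosomal RNA processing factor (2.51 ± 0.16, 0.000309), MTR4, the exosome's helicase (2.47 ± 0.29, 0.000982), USO1, a vesicle tether (2.44 ± 0.35, 0.00203), REA1, an ATPase of large-subunit assembly (2.44 ± 0.44, 0.00459), and SAS10, a small-subunit processome protein (2.42 ± 0.26, 0.000815). NOP13 fell by 2.99 in wild type and was at -0.04 ± 0.41 (SD) in the mutant. SDA1 had the smallest difference in the list (0.01 ± 0.20, SE, adjusted p = 0.964). The list's median spread between spots was 0.0567, 0.0548 and 0.0564 on mutant arrays 1 to 3, against 0.109, 0.0775 and 0.0989 for the lowest of the 4 deleted genes. That of RPD3, which also lacks RNA there, was 0.129, 0.181 and 0.0563.

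Cytosolic ribosomal protein genes were not called as a list (median strain difference 0.13, adjusted p = 0.395), with 17 of 135 higher in the mutant and 6 lower (4 and 1 when adjusted over the list alone). The median was -0.022 without wild-type array 3 and -0.041 without mutant array 3. Without wild-type array 2 the list was called, at 0.24 (adjusted p = 0.0119), and after removal of a trend with gene length at 0.26 (adjusted p = 0.0466). RPS17B (1.66 ± 0.31, SE) and RPS26B (1.66 ± 0.35) were higher in the mutant, and RPL18B was lower (-1.14 ± 0.23). The lists of the polymerases, synthetases and translation factors had weaker falls in the mutant. The median difference was 0.80 for RNA polymerase I and III (14 of 20 genes higher, 0 lower, adjusted p = 0.000232), 0.60 for aminoacyl-tRNA synthetases (10 of 17 higher, 0 lower, adjusted p = 0.00945) and 0.47 for translation factors (20 of 40 higher, 2 lower, adjusted p = 0.00429). Adjusted p with an estimated correlation was 0.827, 0.833 and 0.833. The synthetase call was also lost with fry (adjusted p = 0.0744) and with quantile normalization (0.0814), and the translation factor median was 0.29 without mutant array 3 and 0.70 with arrays centred on the deleted genes. RPA49 (1.84 ± 0.16), RPA135 (1.42 ± 0.18), the lysyl-tRNA synthetase gene KRS1 (1.59 ± 0.21), the threonyl-tRNA synthetase gene THS1 (1.51 ± 0.32) and the initiation factor genes TIF3 (1.60 ± 0.26) and TIF35 (1.54 ± 0.17) differed most in these lists.

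**Figure D2:**
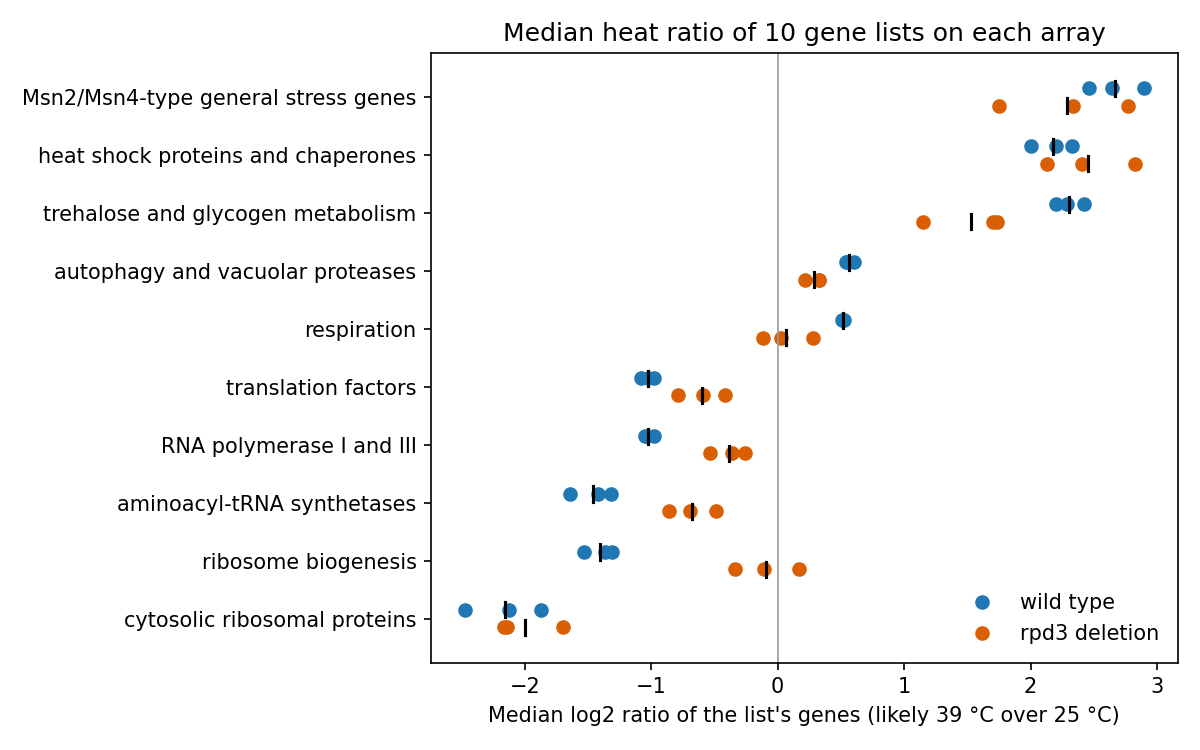
Median log2 heat ratio of the genes of 10 lists on each of the 6 arrays; points are arrays (3 per strain) and black ticks are strain means. The 3 mutant arrays lie above the 3 wild-type arrays for ribosome biogenesis (-0.11, -0.33 and 0.17 against -1.37, -1.53 and -1.31), and the strains overlap for cytosolic ribosomal proteins.

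Genes of stress protection differed in both directions. Of 29 heat shock protein and chaperone genes 16 had a higher ratio in the mutant and 0 a lower one (median 0.78, adjusted p = 0.0013; fry adjusted p = 0.0744; adjusted p = 0.833 with an estimated correlation). The J-protein co-chaperone genes SIS1 (1.83 ± 0.45, SD, in wild type and 3.59 ± 0.37 in the mutant) and YDJ1 (0.82 ± 0.38 and 2.52 ± 0.07) differed most, and SSA1 differed by -0.48 ± 0.23 (SE, adjusted p = 0.124). HSP104 differed by 0.77 ± 0.40 (adjusted p = 0.147), SSA4 by 0.49 ± 0.60 (0.525), HSP12 by 0.60 ± 0.80 (0.561) and HSP26 by -0.17 ± 0.44 (0.769), none of them called. Of 41 general stress genes 14 were lower in the mutant and 1 higher (median -0.37, adjusted p = 0.00931; fry adjusted p = 0.377; adjusted p = 0.948 with an estimated correlation). The median was -0.58 without wild-type array 2, -0.56 without mutant array 2 and -0.13 with arrays centred on the deleted genes. The call was lost without wild-type array 3 (adjusted p = 0.0515) or mutant array 3 (median -0.16, 0.149), with scaled arrays (0.0566) and with quantile normalization (0.161). CTT1 rose by 4.47 ± 0.22 (SD) in wild type and by 2.77 ± 1.01 in the mutant (difference -1.70 ± 0.45, SE, adjusted p = 0.0194), and CMK2, a calmodulin-dependent kinase gene, was higher in the mutant (0.62 ± 0.14).

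The lists of trehalose and glycogen, respiration, and autophagy and vacuolar proteases were shifted down in the mutant, with part of their genes called lower. Of 22 trehalose and glycogen genes 9 were lower and 0 higher (median -0.57, adjusted p = 0.0022; fry adjusted p = 0.0752), with GDB1, the debranching enzyme gene (-1.46 ± 0.25, SE), and PGM2 (-1.33 ± 0.38) differing most, while TPS1 differed by -0.54 ± 0.26 (adjusted p = 0.123). Without mutant array 3 the median was -0.37. Of 45 respiration genes 24 were lower and 2 higher (median -0.48, adjusted p = 2.6e-06), with SDH1 at 1.65 ± 0.14 (SD) in wild type and 0.25 ± 0.24 in the mutant, SDH4 at 1.60 ± 0.32 and 0.12 ± 0.53, and QCR6 higher in the mutant (1.07 ± 0.16, SE). Of 30 autophagy and vacuolar protease genes 12 were lower and 1 higher (median -0.32, adjusted p = 0.00429), led by PRB1 (-1.63 ± 0.28) and the lipase gene ATG15 (-1.31 ± 0.28). Adjusted p with an estimated correlation was 0.833, 0.799 and 0.799 for these 3 lists. With arrays centred on the deleted genes, their medians were -0.33, -0.24 and -0.082, and the respiration median was -0.29 with the length trend removed; the camera calls held in these settings. The lowest strain differences among named genes were those of ERR2 (-3.06 ± 0.15), PHM7 (-2.58 ± 0.49), GRE1, a stress-induced hydrophilin gene (-2.53 ± 0.30), ERR1 (-2.45 ± 0.27), PRY1 (-2.28 ± 0.21), NDE2, a mitochondrial NADH dehydrogenase gene (-2.13 ± 0.31), SPS19, a peroxisomal reductase gene (-2.12 ± 0.26), and TKL2 (-2.09 ± 0.50). ERR1 and ERR2 are close copies of an enolase-related gene, and their spots may read the same RNA. The call for TKL2 was lost without wild-type array 1 (adjusted p = 0.0615) and without moderation of the variance (0.0801).

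**Figure D3:**
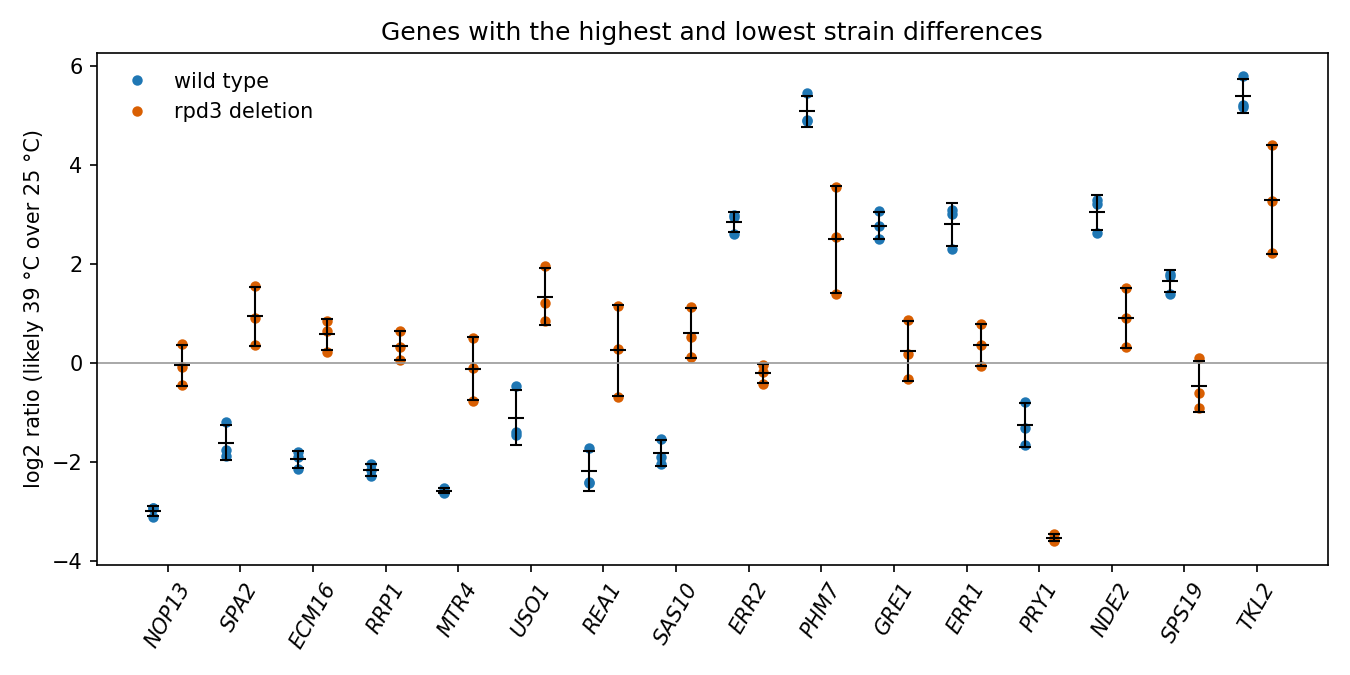
Log2 heat ratio of the 8 genes with the highest and the 8 with the lowest strain difference on each array (points), with the mean and SD over 3 arrays per strain (black). The 3 mutant values of each gene do not overlap its 3 wild-type values, as the rule for these genes requires; ERR2 was at 2.86 ± 0.21 in wild type and -0.21 ± 0.19 in the mutant.

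Among regulators, MSN4 rose in wild type (0.90 ± 0.14, SD) and was at 0.20 ± 0.09 in the mutant (difference -0.70 ± 0.12, SE, adjusted p = 0.0034). MSN2 rose in both strains (0.67 ± 0.15 and 0.61 ± 0.18) and HSF1, the heat shock factor gene, rose in both (0.55 ± 0.07 and 0.36 ± 0.08), with no difference called (adjusted p = 0.740 and 0.151). SIN3, the gene of Rpd3's scaffold partner, was at 0.10 ± 0.18 in wild type and 0.32 ± 0.23 in the mutant (adjusted p of the difference 0.287), UME6 at -0.29 ± 0.10 and -0.25 ± 0.15 (0.792), and the actin gene ACT1 at 0.37 ± 0.05 and 0.55 ± 0.29 (0.366). The list of stress regulators and the protein kinase A pathway was called by fry but not by camera (median -0.20, camera adjusted p = 0.0898, fry adjusted p = 0.0106). In it, TPK2, a kinase subunit gene (-1.24 ± 0.10), and YAK1, a growth-restraining kinase gene (-1.15 ± 0.12), were lower in the mutant. IRA2, a Ras inhibitor gene, was higher (0.85 ± 0.17).

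The remaining lists were not called by camera for the strain difference. The medians were 0.32 for cell cycle genes (adjusted p = 0.0624), -0.17 for oxidative stress defence (0.0949), -0.17 for mitochondrial ribosomal proteins (0.169), -0.26 for the genes deleted in BY4741 (0.169), 0.33 for 7 reference genes (0.258), and between -0.23 and 0.21 for the proteasome (0.716), amino acid synthesis (0.837), the sulfur amino acid pathway (0.705), purine synthesis (0.808), ergosterol synthesis (0.862), glycolysis (0.705), cell wall (0.808), protein folding in the endoplasmic reticulum (0.808), meiosis genes (0.738), mating and cell type (0.744), histones (0.948), hexose transporters (0.716), the phosphate regulon (0.808) and Rpd3-Sin3 complexes (0.716). Fry called the reference genes, a control list (fry adjusted p = 0.00883, as for ribosome biogenesis). It also called oxidative stress defence, the Rpd3-Sin3 complexes and the deleted genes (fry adjusted p = 0.0415 each). A fry call alone thus does not set a list apart from control lists. Median, mean and camera test differed in sign for endoplasmic reticulum folding and for mating genes. They also differed in sign for the sulfur pathway in wild type, and for endoplasmic reticulum folding and the Rpd3-Sin3 complexes in the mutant. Single genes in uncalled lists differed all the same: the Cdk inhibitor gene SIC1 was at -0.03 ± 0.26 (SD) in wild type and 1.36 ± 0.06 in the mutant (adjusted p = 0.000781), and the chaperone gene KAR2 of the endoplasmic reticulum at 1.34 ± 0.25 and 2.80 ± 0.35 (adjusted p = 0.00191).

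Most genes with a 2-fold response in 1 strain were called in the same direction in the other. Of the 350 genes that rose at least 2-fold in wild type, 299 (85.4%) rose in the mutant; the mutant ratio was called lower for 178 (50.9%) and higher for 22 (6.3%). Of the 487 that fell at least 2-fold, 368 (75.6%) fell in the mutant; the fall was called weaker for 240 (49.3%) and stronger for 19 (3.9%). Of the 279 genes that rose at least 2-fold in the mutant, 243 (87.1%) rose in wild type; the mutant ratio was called higher for 87 (31.2%) and lower for 51 (18.3%). Of the 373 that fell at least 2-fold in the mutant, 333 (89.3%) fell in wild type; the mutant fell more for 120 (32.2%) and less for 34 (9.1%). Choosing genes in a strain favours a larger response there, so neither set alone shows which strain responded more. With genes chosen on the other wild-type arrays, the median ratio in the mutant was 70.5% ± 6.43 (SD over the 3 left-out wild-type arrays) of that in the left-out wild-type array for rising genes, and 62.6% ± 6.96 for falling genes. With genes chosen on the mutant arrays, an alternative added after the data were seen, the left-out mutant array stood at 94.0% ± 22.8 (SD over the 3 left-out mutant arrays) and 103% ± 10.6 of the wild-type mean. Equal responses would give mirrored shares for the 2 choices. With genes chosen on the mutant arrays, wild type stood at 111% ± 26.5 of the left-out mutant array for rising genes and 97.8% ± 10.4 for falling genes. The shares were thus not mirrored. A smaller response of the mutant across genes could give this, and so could groups that respond mainly in 1 strain. Of 100 ribosome biogenesis genes, 75 fell at least 2-fold in wild type and 5 in the mutant. The shares also changed with centring and normalization, as given below. Which of these applies was not tested, and the mutant arrays varied widely. Among genes chosen in wild type, the share for rising genes was 61.8% without mutant array 2 and 80.1% without mutant array 3.

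In 289 genes both strains were called in opposite directions with a called difference. Of these, 201 fell in wild type and rose in the mutant and 88 did the reverse. Only USO1 passed 2-fold in both strains, falling by 1.10 ± 0.55 (SD) in wild type and rising by 1.35 ± 0.57 in the mutant. The other genes of this kind named here include SPA2 (-1.60 ± 0.36 and 0.95 ± 0.60), ECM16 (-1.94 ± 0.18 and 0.58 ± 0.32), RRP1 (-2.16 ± 0.12 and 0.35 ± 0.30) and SAS10 (-1.82 ± 0.27 and 0.60 ± 0.50). The count was 145 without mutant array 1, 172 without wild-type array 1 and 160 without wild-type array 2.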

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

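Tests of the gene-length trend, of a weaker overall response and of signals at background level for the ribosome biogenesis genes, and of a background offset and the place near chromosome ends for the PAU and COS genes, were chosen after the results were seen, as were the stricter bound used for cross-hybridisation and the inclusion of RPD3 among the genes without RNA.

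A test of the difference between the strains marked 1012 genes with a higher and 854 with a lower heat ratio in the rpd3 deletion, and 289 genes with opposite calls. Without mutant array 1 these were 643, 450 and 145; without wild-type arrays 1 and 2, 480 and 507 genes were lower and 172 and 160 had opposite calls. The strain difference held 1866 genes in limma, and the other 9 of the 10 splits of the 6 arrays held at most 0, with at most 534 genes at an unadjusted p under 0.05. Of the 10 splits 1, the real one, gave as many. With the sign of 1 array turned, limma called at most 0 genes in either strain, against 2687 in wild type and 2672 in the mutant, with at most 5 and 81 at an unadjusted p under 0.05; in each strain 1 of 4 sign patterns reached the real count. These designs have too few splits for a share under 0.05. The other splits and sign patterns also put the strain difference or the heat response into the residual spread. Their 0 calls therefore do not measure how many real calls are false.

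For the strain difference, camera at its preset correlation marked 9 lists: ribosome biogenesis (median difference 1.25), RNA polymerase I and III (0.80), heat shock proteins and chaperones (0.78), aminoacyl-tRNA synthetases (0.60), translation factors (0.47), autophagy and vacuolar proteases (-0.32), general stress genes (-0.37), respiration (-0.48) and trehalose and glycogen metabolism (-0.57). The limma test of single genes marked NOP13 (2.95), SPA2 (2.55), ECM16 (2.52), RRP1 (2.51), MTR4 (2.47), USO1 (2.44), REA1 (2.44), SAS10 (2.42) and RPS26B (1.66), which were higher in the mutant. Lower in the mutant were ERR2 (-3.06), PHM7 (-2.58), GRE1 (-2.53), ERR1 (-2.45), PRY1 (-2.28), NDE2 (-2.13), SPS19 (-2.12), TKL2 (-2.09), CTT1 (-1.70), DBP2 (-1.50), ATF2 (-1.10), RPL21A (-0.85), MSN4 (-0.70) and RPD3 (-0.29). The value of RPD3 lies at the level of genes without a transcript in the mutant and is close to the median of the deleted genes' differences (-0.26).

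Spots without a gene name here also carried signal. Of 16678 such spots with values, 1736 had a wild-type mean above 1 and 724 below -1. In the mutant 957 lay above 1 and 983 below -1, and 715 and 259 did so in both strains. None of the 28 spots of the deleted genes passed these bounds, and the largest size among them was 0.329.

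All 100 ribosome biogenesis genes fell in wild type, while the list was not called in the mutant, and a trend with gene length is argued against as the whole cause: with each array's trend removed, the median strain difference was 1.30, against 1.25 before, with all mutant arrays above all wild-type arrays. A mutant response weaker by a common factor in both lists is argued against by the quotient of the biogenesis median over the ribosomal protein median. This quotient was 0.642, 0.817 and 0.529 on the wild-type arrays and 0.0499, 0.155 and -0.0991 on the mutant arrays. The gap was 0.375, against a range of at most 0.288 within a strain. The quotient restates list medians that had already been seen. It cannot address a response that differs in timing, which stays open, since the arrays cover a single heating time. Signals at background level for most of the list are argued against by 67 of 100 genes with a mutant mean beyond 0.201 in size. That bound came from the 5 genes taken to be without RNA on the mutant arrays (the deleted genes and RPD3). Of these 67 biogenesis genes, 33 were called lower and 15 higher. Signals near background met the criterion written beforehand for excluding them, as the list's spread between spots was 0.520, 0.707 and 0.571 of the lowest deleted gene's on the mutant arrays; they are left open because that criterion had left out RPD3, which also lacks RNA there and gave 1.00 on mutant array 3, and because the list lay above the lowest deleted gene on the wild-type arrays, where it fell. Also open are the absence of Rpd3, which the design names, and a lower level at 25 °C in the mutant, which ratios cannot show, both untested.

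The PAU genes of cell wall mannoproteins and the COS genes of membrane proteins, chosen after their values were seen, had lower ratios in the mutant: 9 of 9 and 9 of 11 were called lower, with medians of -1.28 and -1.23, and -1.25 over both. An offset of spots at background level is argued against, since the lowest deleted gene stood at -0.29, with an SD of 0.052 over the 4. Cross-hybridisation within the families was to be excluded by any shift of the other genes near chromosome ends; for 48 genes outside families among the outermost 10 of each arm, the median against interior genes shifted by -0.33, with all 3 mutant arrays below all 3 wild-type arrays. That bound was too lenient, because -0.33 is far smaller than -1.25 and leaves room for the families' spots to read shared RNA, so cross-hybridisation stays open. The same shift of -0.33 leaves room for a part of the place near chromosome ends, as a hypothesis found in these data. The medians of these outer genes were 0.27, 0.22 and 0.20 in wild type and -0.06, 0.12 and -0.09 in the mutant. The deleted genes differed by a similar amount (median -0.26), so an offset of spots at background level could also give this shift. Without intensities, place and offset cannot be told apart here. A changed level in the control cells of the mutant, which ratios cannot show, stays open for these families too.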

How the results depend on the processing

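Centring on the deleted genes, removal of a trend with gene length, a filter on the spread between spots and genes chosen in the mutant were chosen after the data were seen; the causes of the changes below were not tested unless given. With fewer genes passing by construction, a 2-fold minimum gave 350 genes higher and 487 lower in wild type, 279 and 373 in the mutant, 296 and 177 for the strain difference, and 1 gene (USO1) with opposite calls. An adjusted p under 0.01 gave 588, 408 and 103 for the last 3 counts. Array weights did not converge and gave mutant array 1 a weight of 145, against at most 1.14 for the others; with them 1984 genes fell in the mutant, 1616 and 1531 differed upwards and downwards between strains, and 824 had opposite calls. Centring on the deleted genes moved the wild-type arrays by their medians of 0.25, 0.12 and 0.06 and the mutant arrays by those of -0.09, -0.08 and -0.12, which changes 0 for every gene, and gave 1564 genes higher and 398 lower for the strain difference. The mutant's median as a share of wild type's was 83.1% for rising and 47.3% for falling genes with this centring, 82.9% and 78.0% with quantile normalization, 78.6% for falling genes of at least 3-fold, and 94.0% and 103% with genes chosen on the mutant arrays, where the choice itself favours the mutant.

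The heat shock protein list (0.78) lost its call with an estimated correlation (adjusted p = 0.833) and with fry (0.0744), the general stress list with an estimated correlation (-0.37, 0.948), fry (-0.37, 0.377), scaled arrays (-0.30, 0.0566) and quantile normalization (-0.20, 0.161), and the ribosome biogenesis list (1.25) with an estimated correlation (0.799). The ribosomal protein list gained a call with the length trend removed (0.26, 0.0466). With single arrays left out, the strain difference held 643 to 1202 genes higher and 450 to 1016 lower, opposite calls ranged from 145 to 384, the shares from 61.8% to 80.1% and from 55.9% to 70.4%, the general stress median from -0.58 to -0.16 and the ribosomal protein median from -0.041 (without mutant array 3, uncalled) to 0.24. Fewer arrays also mean fewer degrees of freedom. The lowest counts were those without mutant array 1; wild-type arrays 1 and 2 gave 480 and 507 genes lower, and 172 and 160 opposite calls.

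With the replicate number as a replicate block, 1131 genes were higher and 962 lower, 1826 of them among the 1866 called without it. Deviations of arrays with the same number correlated with r = -0.22, 0.21 and 0.42 across genes, and the consensus correlation within a block was 0.274. With 3 arrays per strain these values cannot settle whether the numbers pair the cultures, which stays open. Single genes were followed under alternatives only for 40 results. These were the 6 highest and 6 lowest genes of each strain and the 8 highest and 8 lowest strain differences. Of their values under alternatives, 737 stayed on their side of the threshold and 3, all of TKL2, did not. Other values of genes named by the rule, among them the strain differences of CTT1 and RPD3, were not tested in this way. For the other called lists, 565 stayed and 56 lost the call, 41 of these with an estimated correlation. No called direction reversed in any of these. Filters on missing values and on standard names removed no gene and could show nothing. Signal over background was not analysed here, so the limit it sets is unknown.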

Other observations

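The grouping of genes by name and the test of single arrays for the length trend were chosen after the results were seen; the test outside the translation lists and that of the coiled-coil list were written before their results.

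Among 74 groups of genes that share the letters of their name, with at least 8 members each, camera called 12 higher and 10 lower in the mutant; those below were picked after their values were seen. RAD genes of DNA repair were shifted up as a group in the mutant, with part of them called (12 of 27 called higher and 1 lower, median difference 0.31, camera adjusted p = 0.0342). Groups shifted the same way were TAF genes of the general transcription machinery (9 of 14 called higher, 0.54, adjusted p = 0.0108), POL genes, mostly of DNA polymerases (9 of 9, 0.90, adjusted p = 0.0012), and NUP genes of the nuclear pore (8 of 20, 0.29, adjusted p = 0.0342). Shifted down as groups, with part of their genes called, were COX genes of cytochrome oxidase (9 of 21 lower, -0.44, adjusted p = 0.00127), THI genes of thiamine metabolism (9 of 13 lower and 1 higher, -0.40, adjusted p = 0.0317) and TOM genes of protein import into mitochondria (6 of 9 lower, -0.75, adjusted p = 0.0481). With an estimated correlation the adjusted p was 0.712 to 0.722 for these groups. The trend with gene length described next was not removed from these values, so its part in them is unknown.

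The strain difference rose with gene length across 4064 genes (rho = 0.170), with a median of -0.21 in the shortest 10% and 0.21 in the longest 10%. Genes of the 6 lists of ribosomes and translation are argued against as its carriers, as rho was 0.173 over the other 3695 genes. Differences between single arrays could account for it: rho between ratio and length was 0.0535, 0.0496 and 0.147 on the wild-type arrays and 0.288, 0.144 and 0.346 on the mutant arrays, so the lowest mutant array lay 0.0033 below the highest wild-type array (-0.0033). Genes are not independent replicates.

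Genes of long coiled-coil proteins such as USO1, SPA2 and SMC2 (2.17, chosen after its value was seen) stood among the highest differences. A hypothesis is that such genes may shift together. A list of 33 others, written before its test, had a median difference of 0.67, with 23 genes called higher and 0 lower (camera p = 3.67e-06, and p = 0.214 with an estimated correlation of 0.379). The median lay above 100% of 10000 lists matched on length. The tested list left out the genes already seen, but it was drawn up because of them.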
